A study of Mus musculus with 17 samples.

How the data were processed

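The 12 bulk libraries were taken as the authors' deposited tables of raw read counts per gene, made with STAR and HTSeq on mm10 per the submitters' processing notes, with versions not given in the sources used here. The 5 single-cell libraries were taken as the authors' deposited matrices of UMI counts from Cell Ranger, version 3.1.0 per the file headers of 3 of the matrices. The labels describe RNA from an RNeasy kit, and cDNA from iScript. Gene names were compared with GENCODE M21 on GRCm38, which holds the symbols of 46394 of 48397 genes in the bulk tables (95.9%), and the remaining 4.1% name no gene there. The reference is a copy whose build may not be the authors', and mm10 and GRCm38 share coordinates.

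Groups follow the library titles. The treatment field gives PD1_Fc_3 as PDL1 Fc and PDL1_Fc_1 to 3 as PD1 Fc, while the protocol names no PD-L1 Fc, so alternatives by the treatment field and without these 4 libraries were run. File names of 2 single-cell libraries, flWT_CD4Cre and WT, disagree with their labels, and the labels were used. The pair flfl_CD4Cre and CD4Cre is not affected. Groups, alternatives, gene lists, the comparisons and the rule for naming genes were fixed before the data were examined. Tests and alternatives chosen later are named as such where they appear.

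Bulk counts were fitted with edgeR 4.0.16 (R 4.3.3) on all 12 libraries together, with TMM factors, the default expression filter and robust quasi-likelihood tests, which left 14653 genes. Adjusted p-values are Benjamini-Hochberg values, and SE is the size of the log2 change over the square root of F. Alternatives were DESeq2 1.42.0, DESeq2 size factors, no filter, only the libraries compared, the replicate number as a block, and omission of each library in turn. Lists of 30 gene groups, written from general knowledge, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation. List medians use members with at least 5 CPM. A fold against a group with 0 counts is given as a floor from 3 counts over that group, and floors cover counting error only. Splits of the same 6 libraries into 3 and 3 were refitted in all 10 ways, and 100 splits were drawn for the difference of differences.

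Named bulk genes are Cd274, Pdcd1 and Cd80, then genes past an adjusted p of 0.05 with groups that do not overlap and at least 5 CPM in the higher group, the 10 largest changes each way for PD1_Fc against Ctrl_Fc, 5 for other comparisons and 3 for the difference of differences. Where none passed, the 5 smallest p each way were named as not passing. Up to 4 members per list with the smallest p were also reported for PD1_Fc against Ctrl_Fc. Gene models, clones, pseudogene names, receptor segments, mitochondrial and histone genes were not named under the size rule. A result that the rule would name was withheld for evaluation and is left out. B2m and Saa3, and the marker and list genes given by level such as Lyz2, Cd3e and Lat, were chosen after their values were seen.

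Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, and the highest Scrublet scores were removed up to 0.8% per 1000 cells, with scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). The 28208 genes common to the libraries were used, with 2000 variable genes, 30 components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.0, which gave 37 clusters. A cluster took the name of the best of 17 marker classes when at least 3 markers passed, and was left unnamed otherwise. It was also left unnamed when its top 10 genes held more markers of another class. The same held for a cluster shallow in UMIs with no marker of its class among those genes. Levels are summed counts of a class as CPM, with Poisson intervals for levels and exact binomial intervals for shares, both at 95%. List medians are ranked among 10000 random lists matched on expression. Genes were named by size at 50 CPM or more, a change of at least 1 log2 between flfl_CD4Cre and CD4Cre, intervals that do not overlap, and a level in flfl_CD4Cre outside those of the other 4 libraries.

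The calling steps were tested on simulated data. For PD1_Fc against Ctrl_Fc, 64% of 1.5-fold, 86% of 2-fold and 96% of 4-fold changes were recovered among 200 changed genes, with 7 false calls. For PDL1_Fc against Control the shares were 93%, 98% and 96% with 16 false calls. For the single-cell pair, 0% of 1.5-fold, 100% of 3-fold and 96% of 4-fold changes among 3203 genes were named, with 0 unchanged genes named. Lists shifted by 0.5 and -0.5 log2 took percentiles 100 and 0, and 3 of 26 lists left alone fell outside the central 95%. Replicate libraries were checked for duplication, and chi-square per degree of freedom ran from 1.56 to 20.3 with no identical pair.

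Sequence reads were not used here, nor was any further cell-type reference. Unaligned reads are not part of the count tables and were not analysed here. The flow cytometry named in the labels was not analysed here.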

Results

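The series holds 12 bulk RNA libraries, 3 in each of 4 groups titled Control, Ctrl_Fc, PD1_Fc and PDL1_Fc, all labelled as wild-type mouse splenic T cells stimulated through CD3 and CD28. PD-1 Fc is a soluble form of the receptor that binds PD-L1, the protein encoded by Cd274, so the bulk groups ask what binding of PD-L1 on activated T cells does to their RNA. It also holds 5 single-cell libraries from mouse pancreatic tumours, which the labels describe both as sorted leukocytes and as tumour-infiltrating T cells, 1 each from mice titled CD4Cre, flWT_CD4Cre, flfl_CD4Cre, flfl and WT, where Cre under the Cd4 promoter is meant to remove floxed Cd274 from T cells. Nothing in the sources says that the bulk libraries come from separate animals or cultures, so their p-values may measure technical spread.

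Bulk libraries held 17.9 M gene counts on average in Control (SD 1.05, n = 3), 15.4 in PDL1_Fc (SD 0.575, n = 3), 4.01 in Ctrl_Fc (SD 0.603, n = 3) and 4.75 in PD1_Fc (SD 0.337, n = 3). Reads without an alignment made up 10.1% of Control and 9.96% of PDL1_Fc reads but 80.2% of Ctrl_Fc and 80.1% of PD1_Fc reads. After filtering, the single-cell libraries held 5358 cells (CD4Cre), 4225 (flfl_CD4Cre), 4386 (flWT_CD4Cre), 2796 (flfl) and 2813 (WT). Median UMIs per cell were 4844, 10950, 5037, 10764.5 and 11136 in the same order.

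The 12 bulk libraries fell into 2 sets, which differ in macrophage and T cell markers. Lyz2, the lysozyme of macrophages, stood at 21379.9 CPM in Control (SD 3759, n = 3) and 21579.8 CPM in PDL1_Fc (SD 935, n = 3), against 63.8 CPM in Ctrl_Fc (SD 57.4, n = 3) and 66.04 CPM in PD1_Fc (SD 51.9, n = 3). Cd3e, a subunit of the T cell receptor complex, was at 258 CPM in Ctrl_Fc (SD 14.8) and 248 CPM in PD1_Fc (SD 17.2), but at 0.0360 CPM in Control and 0.110 CPM in PDL1_Fc. Trac, the receptor alpha constant gene, had 1118 counts in Ctrl_Fc, 1392 in PD1_Fc, 0 in Control and 3 in PDL1_Fc. Not all T cell genes were present, as Cd3d, another subunit, had 0 counts in Ctrl_Fc and PD1_Fc, and Cd8b1, Ptprcap and Ms4a4b were at 0 CPM there. The median of 9 macrophage markers lay between 94.7 and 120.2 CPM in every Control and PDL1_Fc library and between 0.288 and 0.858 CPM in every Ctrl_Fc and PD1_Fc library. B2m, the light chain of MHC class I on nearly all nucleated cells, was at 12539 CPM in Control and 12900.4 CPM in PDL1_Fc but at 37.1 CPM in Ctrl_Fc (SD 39.96) and 37.7 CPM in PD1_Fc (SD 32.3), a level below that of Cd3e.

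**Figure D1:**
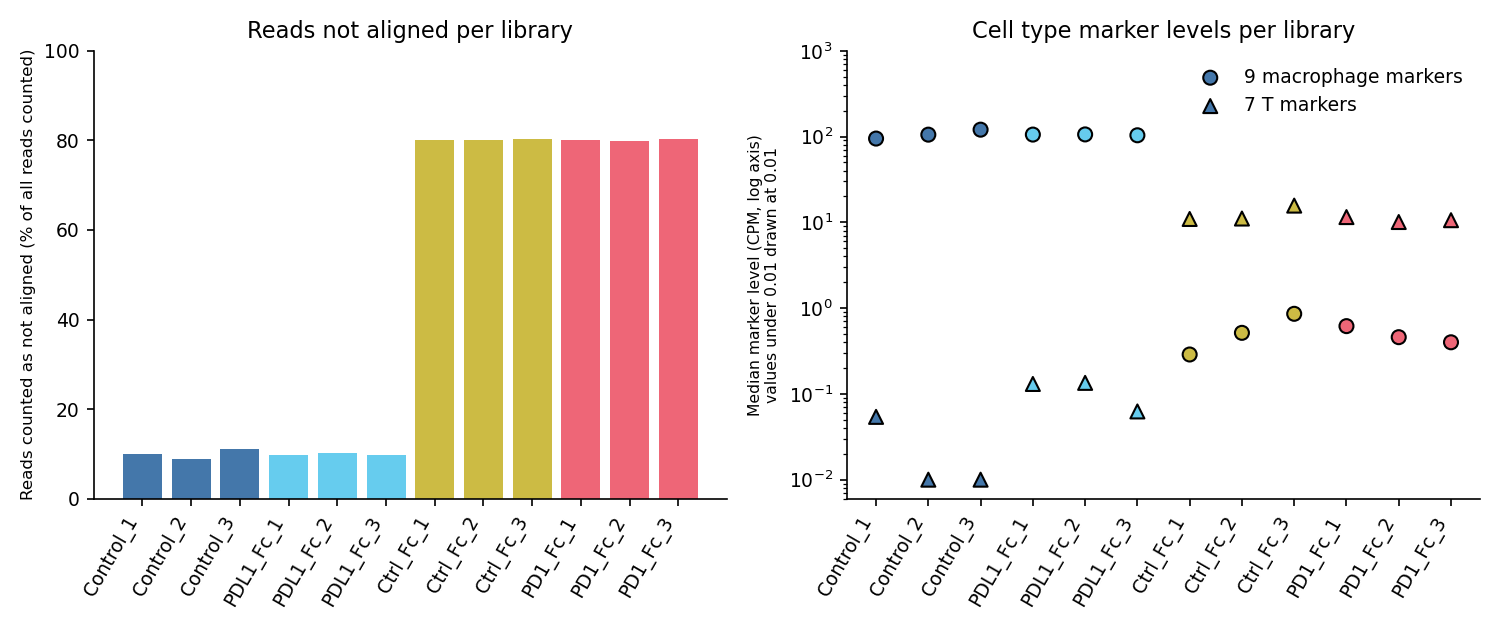
Left, percent of reads not aligned in each of the 12 bulk libraries, from group means of 9.96% to 80.2%. Right, median CPM on a log axis of 9 macrophage markers (circles) and 7 T cell markers (triangles) per library, with values under 0.01 drawn at 0.01.

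The comparison of PD1_Fc with Ctrl_Fc asks what soluble PD-1 changes in stimulated T cells beyond a control Fc. In both groups about 80% of reads were not aligned, so whether the counted reads all come from mouse T cells stays open. Traf6, a ubiquitin ligase that carries Toll-like and CD40 signals to NF-kB, rose by 1.03 log2 (SE 0.20, edgeR adjusted p = 0.0144, 15.05 against 7.55 CPM, n = 3 and 3). Ddx60, an interferon-induced helicase that aids viral RNA sensing, fell by 1.00 log2 (SE 0.20, adjusted p = 0.0179, 7.51 against 15.8 CPM). Mx2, an interferon-induced GTPase gene annotated in mouse as a polymorphic pseudogene, fell by 0.72 log2 (SE 0.16, adjusted p = 0.0414, 15.3 against 26.6 CPM). Of 14653 genes tested, 7 passed, 1 higher and 6 lower, and 771 had an unadjusted p under 0.05. All 7 had groups that did not overlap, a pattern that 10% of unchanged genes give with 3 libraries a side. The other 4 have names of gene models or pseudogenes, namely Gm12011 (fell by 0.83 log2, SE 0.16), Gm15148 (fell by 1.05, SE 0.23), Gm9372 (fell by 0.60, SE 0.11) and Rps12-ps1 (fell by 0.51, SE 0.10). DESeq2 called 21 genes, of which 3 were among these 7, and gave no adjusted p for Traf6 or Ddx60. On GRCm38, Traf6 lies at chromosome 2, 101678429 to 101701669, Ddx60 at chromosome 8, 61928087 to 62038244, and Mx2 at chromosome 16, 97535308 to 97560900.

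Most calls were lost with 1 library fewer. Without Ctrl_Fc_1, Ctrl_Fc_2 or PD1_Fc_2 no gene passed, without PD1_Fc_1 or PD1_Fc_3 just 1 did, and without Ctrl_Fc_3 there were 8, 5 of them shared. The change of Traf6 was at least 0.86 log2 in every alternative. Ddx60 lost its call without any 1 of the 6 libraries, with adjusted p from 0.0549 to 0.260 across those omissions and from 0.00603 to 0.288 across all alternatives. Of the 6 omissions, Traf6 kept its call only without Ctrl_Fc_3 (adjusted p = 0.00271) and lost it without Ctrl_Fc_1 (0.340), Ctrl_Fc_2 (0.344), PD1_Fc_1 (0.0704), PD1_Fc_2 (0.0869) or PD1_Fc_3 (0.240), with a range of 0.00271 to 0.486 over all alternatives. Mx2 kept it only without PD1_Fc_1 (0.0151) and lost it without Ctrl_Fc_1 (0.315), Ctrl_Fc_2 (0.255), Ctrl_Fc_3 (0.107), PD1_Fc_2 (0.535) or PD1_Fc_3 (0.558), with a range of 1.6e-04 to 0.558. The 3 levels of Traf6 in PD1_Fc were all above those in Ctrl_Fc, and the 3 levels of Ddx60 and Mx2 were all below.

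**Figure D2:**
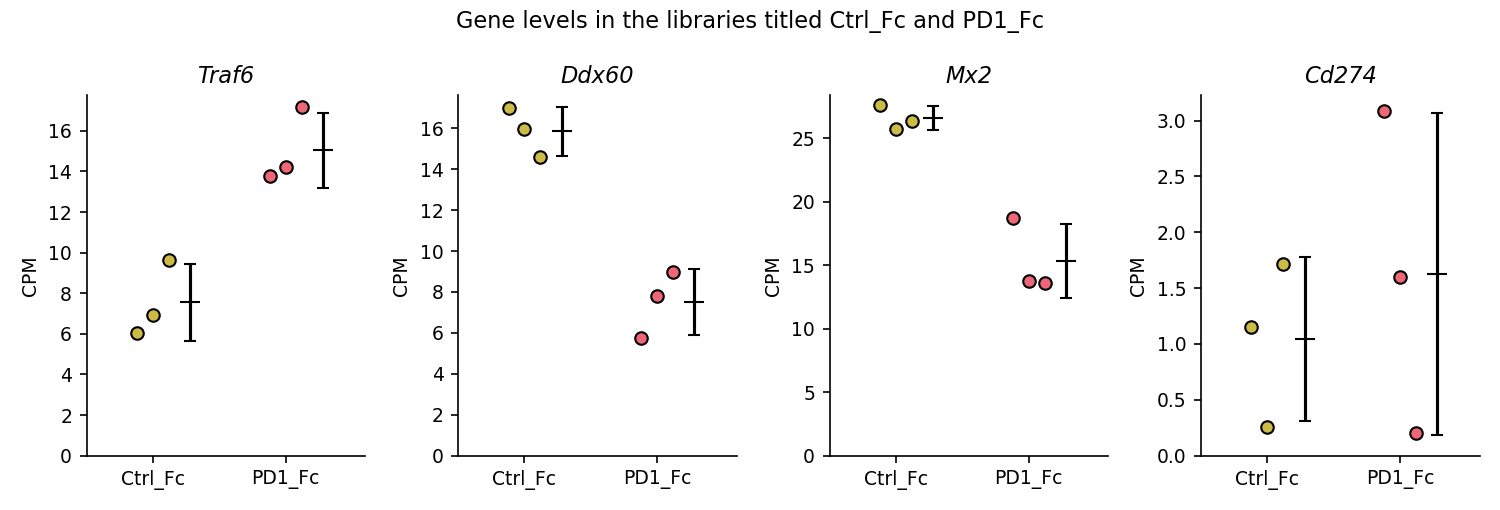
CPM of Traf6, Ddx60, Mx2 and Cd274 in each Ctrl_Fc and PD1_Fc library. Bars give the group mean with SD, for example 7.51 (PD1_Fc) and 15.8 CPM (Ctrl_Fc) for Ddx60.

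Cd274 and its partner genes had few or no counts in the Ctrl_Fc and PD1_Fc libraries. B2m, a gene of nearly all nucleated cells, was also low there (37.1 and 37.7 CPM). Low counts here therefore do not show that the T cells lacked these RNAs. Cd274 had 13 counts over the 3 Ctrl_Fc libraries and 23 over the 3 PD1_Fc libraries, or 1.04 and 1.63 CPM (log2 0.63, SE 0.57, edgeR adjusted p = 0.932, from 0.0880 to 1 over the alternatives). Of these counts 8 were in Ctrl_Fc_3 and 15 in PD1_Fc_1, the libraries with an excess of Lyz2. Without PD1_Fc_1 the change of Cd274 was -0.31 log2. Cd80, a ligand of CD28 that also binds PD-L1, had 2 and 3 counts (log2 0.37, SE 1.24, adjusted p = 1). Pdcd1, the PD-1 gene, had 0 counts in both groups and was not tested. Cd274 lies at chromosome 19, 29367455 to 29388095, Pdcd1 at chromosome 1, 94038305 to 94052553, and Cd80 at chromosome 16, 38455561 to 38496335.

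Stress, cell cycle, B cell and interferon gamma genes moved as lists. The unfolded protein and amino acid stress list rose, with 17 of 18 members higher and a median of 0.20 log2 (camera adjusted p = 1.05e-04, adjusted p = 0.649 with an estimated correlation). Psat1, an enzyme of serine synthesis, led it (log2 0.51, SE 0.15, 35.6 against 25.9 CPM, edgeR adjusted p = 0.444), ahead of Asns, Herpud1 and Slc7a11. The cell cycle list rose, with 22 of 25 members higher and a median of 0.15 log2 (adjusted p = 4.98e-04, 0.649 with an estimated correlation), among them the kinesin Cenpe (log2 0.57, SE 0.21, adjusted p = 0.911) and the replication helicase subunit Mcm6 (log2 0.24, 793 against 704 CPM, adjusted p = 0.919). The B cell list fell, with 7 of 9 members lower and a median of -0.33 log2 over the 3 members at 5 CPM (adjusted p = 0.0361, 0.536 with an estimated correlation, 0.108 with only the 6 libraries and 0.164 without Ctrl_Fc_3 and PD1_Fc_1), led by the B lineage factor Pax5 (log2 -0.93, SE 0.33, 4.65 against 9.28 CPM, adjusted p = 0.889). The interferon gamma list fell, with 13 of 20 members lower and a median of -0.03 log2 (adjusted p = 0.0361, 0.884 with an estimated correlation), led by the immunoproteasome subunit Psmb9 (log2 -0.57, SE 0.15, 20.2 against 31.3 CPM, adjusted p = 0.260). Adjusted over all genes no member of these 4 lists passed, and adjusted over each list alone Psat1 rose and Psmb9 fell. The estimated correlation left 0 of 30 lists.

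The type I interferon list did not pass (camera adjusted p = 0.0819, adjusted p = 0.884 with an estimated correlation), although 5 of its 7 members at 5 CPM were lower, with a median of -0.37 log2. Mx1, an interferon-induced antiviral GTPase, was at 10.6 CPM in PD1_Fc and 17.5 CPM in Ctrl_Fc (log2 -0.67, SE 0.19, edgeR adjusted p = 0.386), and it passed when adjusted over its list alone. Ifih1, a sensor of double-stranded RNA, was at 32.9 and 44.4 CPM (log2 -0.38, adjusted p = 0.919). The Th1 list had 10 of 15 members lower (adjusted p = 0.0602), with the master factor Tbx21 at 68.9 and 82.6 CPM (log2 -0.20).

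T cell function lists gave no call. Effector genes had 7 of 12 members higher with a median of 0.07 log2 while the camera test pointed down (adjusted p = 0.501), among them the granzyme Gzmb (log2 -0.26, 20.4 against 25.4 CPM) and Lta (log2 -0.13). Th2 genes had 6 of 7 members higher (adjusted p = 0.354), Th17 genes 5 of 9 lower (0.608), and regulatory T cell genes 12 of 18 higher (0.759), with the brake receptor Ctla4 at 84.6 and 70.5 CPM (log2 0.33, SE 0.13, edgeR adjusted p = 0.919). Anergy genes had 11 of 17 members higher (0.787), with the ligases Cblb (log2 0.18) and Itch (log2 0.14) slightly higher and the anergy factor Egr2 lower (log2 -0.24, 87.4 against 108 CPM). Inhibitory receptor genes had 6 members higher and 6 lower (0.888), and receptor activation genes 9 higher and 8 lower (0.759). Naive and memory genes had 9 of 14 members higher (0.987), with the factor Satb1 at 808 and 736 CPM and the factor Tcf7 at 243 and 291 CPM. CD4 lineage (0.728), CD8 lineage (0.501) and natural killer genes (0.759) did not pass.

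Metabolic and signalling lists were also quiet. Nuclear respiratory chain genes had 16 of 20 members higher (camera adjusted p = 0.481) and glycolysis genes 13 of 18 higher (0.501), with the lactate dehydrogenase Ldha at 109.9 and 100.1 CPM. Hypoxia genes had 9 of 14 members higher (0.554), cholesterol synthesis genes 8 of 18 higher with a test pointing down (0.554), and p53 genes 9 of 16 lower (0.833). NF-kB targets had 9 of 15 members lower (0.370), and STAT feedback genes 7 higher and 7 lower (0.608). Myeloid lists did not pass either, namely macrophage (0.552), inflammatory macrophage (0.121), alternative macrophage (0.787), dendritic (0.425), neutrophil (0.9503) and erythroid or platelet (0.212). Ccl22, a chemokine of alternatively activated macrophages, had 1 count in PD1_Fc and 11 in Ctrl_Fc (edgeR adjusted p = 0.646) and passed only when adjusted over its list alone.

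**Figure D3:**
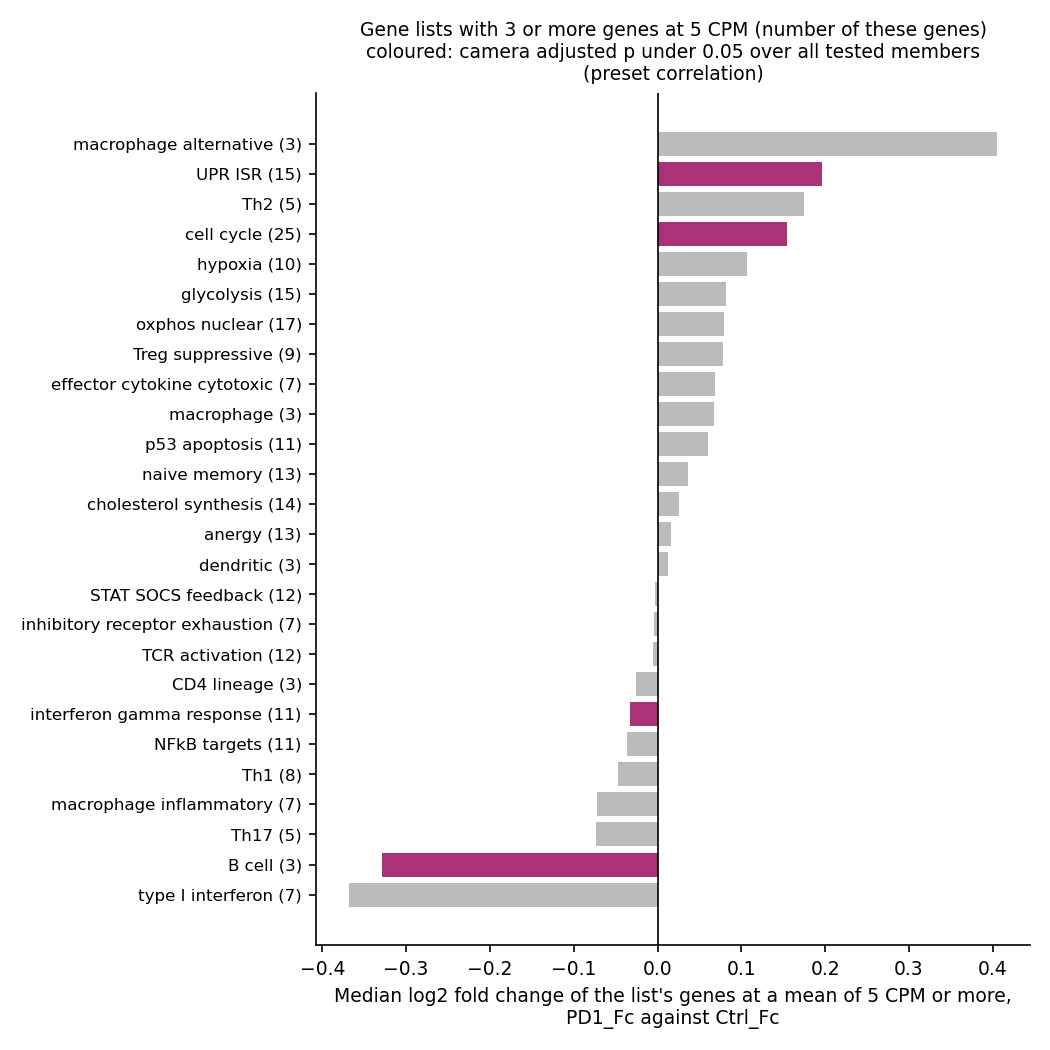
Median log2 fold change in PD1_Fc against Ctrl_Fc over the members at 5 CPM of 26 gene lists, from -0.37 for type I interferon genes to 0.41 for alternative macrophage genes. Coloured bars are the lists with a camera adjusted p under 0.05 over all tested members.

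The comparison of PDL1_Fc with Control sets a group titled for PD-L1 Fc against stimulation alone. None of 14653 genes passed by edgeR or by DESeq2, and 528 had an unadjusted edgeR p under 0.05. Cx3cr1, the fractalkine receptor of monocytes and macrophages, came closest, at 4.34 CPM in PDL1_Fc and 8.87 CPM in Control (log2 -1.04, SE 0.22, adjusted p = 0.296), with overlapping groups. Its adjusted p ran from 7.3e-05 without Control_3 to 1 over the alternatives, and it was 0.00611 without the gene filter. Pou2f2, a factor of B cells and macrophages, was at 30.8 and 22.5 CPM (log2 0.45, SE 0.11, adjusted p = 0.489), and the macrophage factor Maf at 24.5 and 18.2 CPM (log2 0.42, SE 0.11, adjusted p = 0.489). Gclc, of glutathione synthesis, was at 49.1 and 36.9 CPM (log2 0.41, SE 0.11, adjusted p = 0.557). Slain1 had 0 counts against 14 (at least 4.01-fold lower, adjusted p = 0.459) and Mrc2, a collagen receptor, 1 against 15 (adjusted p = 0.713). Also named by their small p are Ccdc166 (log2 1.52), Dzip3 (log2 0.81), Mboat2 (log2 -0.91) and Rnf144a (log2 -1.01). Cd274 was at 398 and 413 CPM (log2 -0.06, SE 0.10, adjusted p = 1) and Cd80 at 54.3 and 62.1 CPM (log2 -0.20, SE 0.11, adjusted p = 1). No list passed, the lowest camera adjusted p being 0.115 for Th2 genes, and 0.968 with an estimated correlation. Adjusted over the list alone 1 member rose in each of the Th2, anergy and CD8 lineage lists. In simulated data 93% of 1.5-fold changes were recovered against 64% for PD1_Fc and Ctrl_Fc. The simulation gave all groups the same spread per gene, so this gap does not cover spread in the real libraries. Real Control pairs had a chi-square per degree of freedom of 9.35 to 20.3, against 2.72 to 4.38 in PDL1_Fc, so power here may be lower. Trac had 0 counts in Control and 3 in PDL1_Fc, so the absence of calls does not bear on T cells.

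Ctrl_Fc against Control, PDL1_Fc against Ctrl_Fc and PD1_Fc against PDL1_Fc each cross the 2 sets and measure the set together with the treatment. In Ctrl_Fc against Control 13452 genes passed, 6502 higher and 6950 lower, 13221 of them with groups that did not overlap. The largest increases included the T lineage factor Bcl11b at 125 CPM (at least 2242-fold), the adaptor Skap1 at 99.6 CPM (at least 1791-fold) and Trac at 93.7 CPM (at least 1669-fold). Pabpc2, a poly(A)-binding protein gene expressed in testis, was also among them, at 155 CPM (at least 2770.1-fold). With 80.2% of Ctrl_Fc reads not aligned, its counts may come from reads of other genes, which was not tested. Lower genes included Rhov at 173 CPM in Control (at least 693-fold), the interferon-induced Ifi205 (at least 403-fold), the purine oxidase Xdh (at least 387-fold), Rab7b (at least 292-fold) and the complement regulator Cr1l (at least 283-fold). Cd274 was lower by 9.30 log2 (SE 0.21, edgeR adjusted p = 6.99e-39) and Cd80 by 9.14 log2 (SE 0.30). Of 30 lists 12 passed the camera test and 0 with an estimated correlation (adjusted p from 0.283 to 0.287 among the 12). Cell cycle genes rose (22 of 25 members, 2 fell, camera adjusted p = 5.55e-06), as did naive and memory genes (11 of 14, 3 fell, 0.0106). All 20 type I interferon members fell (9.01e-07), as did all 13 macrophage, 16 inflammatory macrophage, 13 alternative macrophage, 14 hypoxia and 6 dendritic members, 18 of 20 interferon gamma, 15 of 18 glycolysis, 12 of 15 NF-kB and 14 of 16 p53 members.

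PDL1_Fc against Ctrl_Fc gave the mirror image, with 13443 genes (6952 higher, 6491 lower, 13269 not overlapping). Cd274 rose by 9.24 log2 (SE 0.21, edgeR adjusted p = 1.05e-38) and Cd80 by 8.94 log2 (SE 0.31). Rhov (at least 633-fold), Ifi205 (416), Xdh (373), Rab7b (328) and Cr1l (288) were higher. Mt4, a metallothionein of stratified epithelium, was lower at least 3155-fold from 205 CPM, with Pabpc2 (2379), Skap1 (1538), the imprinted splicing gene Snrpn (1425) and the cardiac actin Actc1, which fell by 12.87 log2 (SE 0.22, 0.109 against 1491 CPM). Whether the Ctrl_Fc counts of Mt4 and Actc1 come from reads of other genes was not tested either. Here too 12 lists passed, 10 higher and 2 lower, and 0 did so with an estimated correlation.

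PD1_Fc against PDL1_Fc gave 13455 genes (6592 higher, 6863 lower, 13326 not overlapping), again with Mt4 (at least 2789-fold), Pabpc2 (2279), Snrpn (1598), Skap1 (1489) and Actc1 (log2 12.93) higher. The kinetochore gene Zwint (at least 428-fold), Zfand2a (399.9), Sfr1 (324), Gng12 (279.6) and Mrpl24 (249.7) were lower. Cd274 fell by 8.60 log2 (SE 0.20, edgeR adjusted p = 6.02e-39) and Cd80 by 8.57 log2 (SE 0.29). The 12 lists that passed were again lost with an estimated correlation. Within the sets 7 and 0 genes passed, so most of these 13455 changes go with the set. An Fc effect shared by Ctrl_Fc and PD1_Fc cannot be told apart from the set.

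The difference of differences asks whether PD1_Fc against Ctrl_Fc departs from PDL1_Fc against Control. Ddx60 alone passed, with a difference of -1.24 log2 (SE 0.23, edgeR adjusted p = 0.0159), while 802 genes had an unadjusted p under 0.05 and DESeq2 called 10. The call was lost without Ctrl_Fc_1 (0.189), PD1_Fc_1 (0.200), PD1_Fc_2 (0.179) or PDL1_Fc_2 (0.0878), and its adjusted p ran from 0.00124 to 0.200 over the alternatives. Cd274 (log2 0.69, SE 0.58, adjusted p = 0.929) and Cd80 (log2 0.57, SE 1.28, adjusted p = 1.00) did not pass. Cell cycle (22 of 25 members, camera adjusted p = 0.00310) and stress genes (15 of 18, 0.0104) were higher, each with an adjusted p of 0.996 with an estimated correlation.

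In the tumours, the question was whether Cd274 loss in T cells changes which leukocytes are present and how macrophages behave. The closest pair is flfl_CD4Cre against CD4Cre, which shares its gene table and lowest UMI count per cell with flWT_CD4Cre. The flfl and WT libraries share another gene table and form a second batch. By the labels, batch and Cre cannot be told apart across the 5 libraries. The file names of flWT_CD4Cre and WT disagree with these labels. Each genotype is 1 library, so there is no test, and intervals cover counting error only. B-like cells made up 41.2% of CD4Cre (39.8 to 42.5), 4.59% of flfl_CD4Cre (3.98 to 5.27), 2.62% of flWT_CD4Cre, 5.29% of flfl and 8.14% of WT cells, so the high share is that of the CD4Cre library, where cluster 0 held 2037 of the 2205 cells. Macrophage-like cells made up 21.6% of flfl_CD4Cre (20.3 to 22.8), 9.67% of CD4Cre (8.89 to 10.5), 8.34% of flWT_CD4Cre, 36.6% of flfl and 51.5% of WT, mostly cluster 4 in the Cre libraries and cluster 2 in flfl and WT. The difference of 11.9 points between flfl_CD4Cre and CD4Cre became 21.9 with each library clustered alone. The shares were then 35.2% of flfl_CD4Cre, 13.3% of CD4Cre, 24.2% of flWT_CD4Cre, 32.1% of flfl and 35.1% of WT. The low share of flWT_CD4Cre thus depends on the clustering. T-like cells were 21.9% of flfl and 15.04% of WT cells but 8, 4 and 14 cells in CD4Cre, flfl_CD4Cre and flWT_CD4Cre. Cluster 27, a T and natural killer group found only in the Cre libraries, was left unnamed because its top genes held more natural killer markers. It was added to the T lineage after the clusters were seen. With it, T lineage cells came to 2.41% of CD4Cre (2.01 to 2.85), 1.66% of flfl_CD4Cre (1.29 to 2.09) and 1.69% of flWT_CD4Cre. Epithelial or tumour cells, which a sort of leukocytes should remove, numbered 507 in flfl_CD4Cre and 122 in CD4Cre and made up 14.5% of flWT_CD4Cre. The lowest UMI count per barcode was 500 in the Cre libraries but 4455 in flfl and 5007 in WT, so class shares are not like for like across batches. Apart from cluster 27, clusters left unnamed held 23.3%, 26.1% and 38.5% of the CD4Cre, flfl_CD4Cre and flWT_CD4Cre cells against 0.858% in flfl and 1.85% in WT. Of these, clusters 1, 6, 10, 12 and 32 were unnamed as shallow, with median UMIs from 702 to 1231. Clusters 6 and 12 among them score as macrophage and held 216 and 28 cells of flfl_CD4Cre, 117 and 109 of CD4Cre, and 563 and 268 of flWT_CD4Cre. Clusters 1 and 10 score as epithelial or tumour. They held 656 and 149 cells of flfl_CD4Cre, 793 and 191 of CD4Cre, and 601 and 137 of flWT_CD4Cre.

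**Figure D4:**
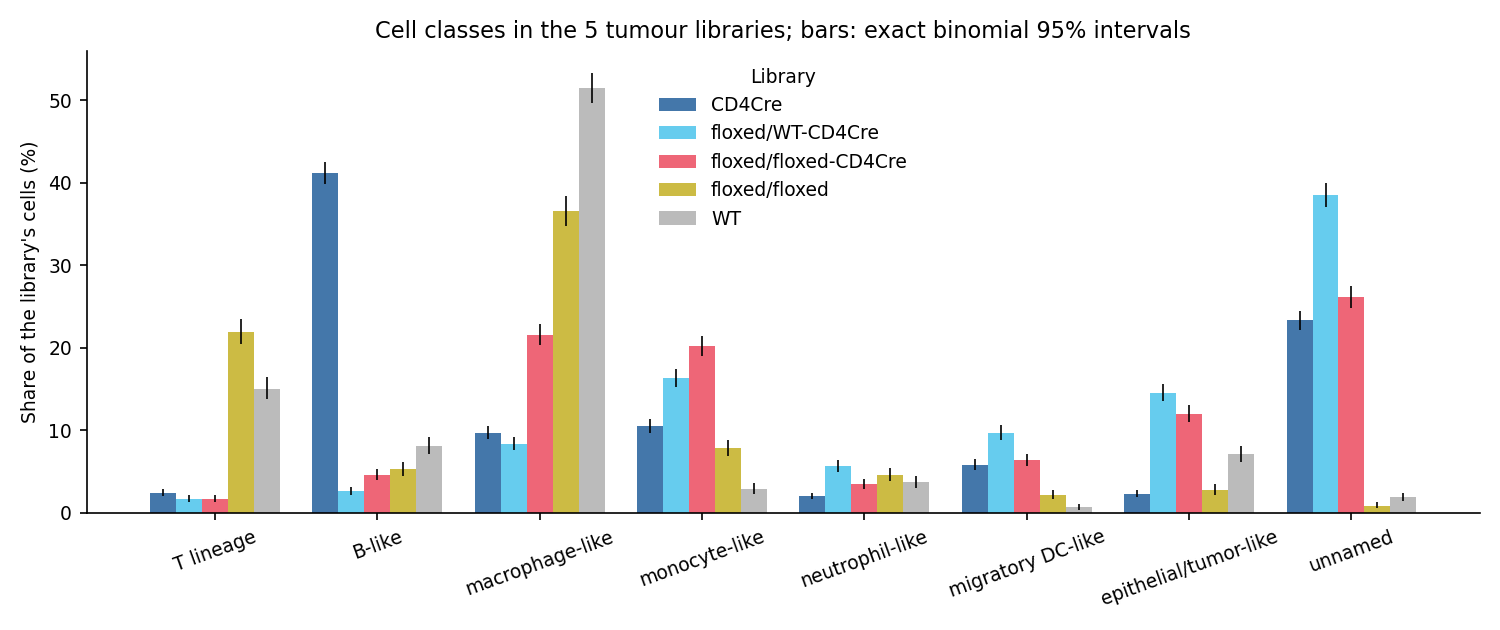
Percent of cells per class in each of the 5 single-cell libraries with exact binomial intervals, for example B-like cells at 41.2% in CD4Cre and 4.59% in flfl_CD4Cre. Each point is 1 library.

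Cd274 UMIs were few in the T lineage of the Cre libraries. In cluster 27 they stood at 45.9 CPM in CD4Cre (31.8 to 64.1, 34 UMIs), 47.7 CPM in flfl_CD4Cre (28.7 to 74.5, 19 UMIs) and 53.2 CPM in flWT_CD4Cre (33.7 to 79.8, 23 UMIs), and in T-like cells at 10.4 CPM in flfl and 8.76 CPM in WT. These reads come from the 3' end, and the deleted exon is not given in the sources used here, so they do not check the deletion. Free RNA of other cells is not excluded as their source, since neutrophil-like cells of these libraries had 578 to 2033 CPM and cluster 27 also held B cell RNA. Pdcd1 in cluster 27 was at 239 CPM in CD4Cre (205 to 277), 118 CPM in flfl_CD4Cre (86.7 to 157) and 224 CPM in flWT_CD4Cre (182 to 274), and in T-like cells at 361 CPM in flfl and 299.6 CPM in WT. Cd80 there had 16, 0 and 3 UMIs in CD4Cre, flfl_CD4Cre and flWT_CD4Cre. In macrophage-like cells Cd274 was at 129 CPM in flfl_CD4Cre (124 to 134), 146 CPM in CD4Cre (138 to 155), 180 CPM in flWT_CD4Cre (170 to 191), 39.6 CPM in flfl and 32.2 CPM in WT. The ratio of flfl_CD4Cre to CD4Cre, -0.18 log2, reversed to 0.0757 without cluster 20 and was -0.54 with monocytes added. Cd80 in these cells was at 18.6 CPM in flfl_CD4Cre, 27.4 in CD4Cre, 19.6 in flWT_CD4Cre, 14.2 in flfl and 10.3 in WT, and Pdcd1 had 1, 18, 0, 83 and 74 UMIs in the same order. Thinned to 1000 UMIs a cell, 12.6% of flfl_CD4Cre and 14.9% of CD4Cre macrophage-like cells had a Cd274 UMI (66.5% and 68.1% before thinning, at median depths of 18766 and 14236, with 13 and 14 cells left out). In epithelial or tumour cells, with median depths of 37256 and 30112, the thinned shares were 1.58% and 2.46%.

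**Figure D5:**
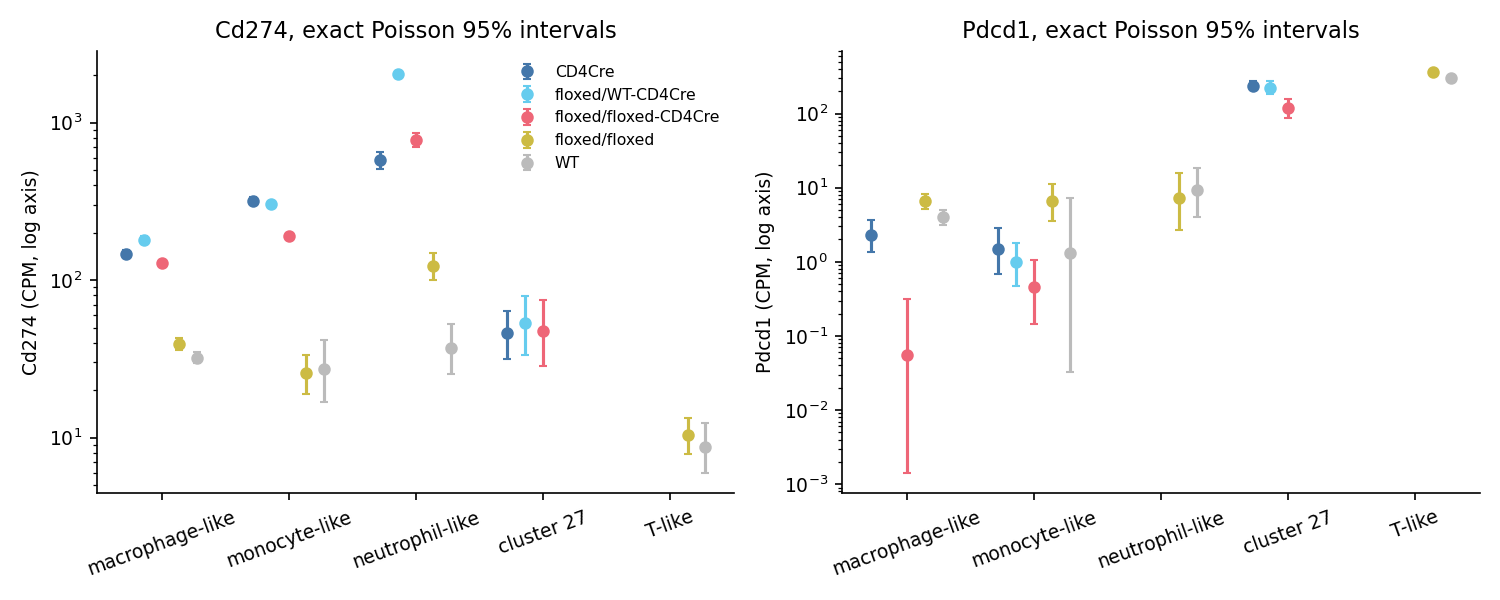
CPM on a log axis of Cd274 and Pdcd1 in macrophage-like, monocyte-like, neutrophil-like, cluster 27 and T-like cells of each library with Poisson intervals, for example 129 CPM of Cd274 in flfl_CD4Cre macrophages. Groups with 0 counts or under 20 cells are not drawn.

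Macrophage-like cells of flfl_CD4Cre carried more interferon gamma target RNA than those of CD4Cre, and less RNA of B cells (7 of 7 members lower, -4.24 log2) and neutrophils (5 of 5 lower, -0.93 log2). The interferon gamma list had 18 of 20 members higher and a median of 0.24 log2 (percentile 99.97 of 10000 matched random lists), and the inflammatory macrophage list 9 of 13 higher and 0.35 log2 (percentile 99.99). Gbp2, a GTPase induced by interferon gamma, was at 571 CPM (559.6 to 582) against 320.1 CPM (308 to 333), the interferon factor Irf1 at 262 against 203 CPM, the nitric oxide synthase Nos2 at 73.0 (69.1 to 77.1) against 38.7 CPM (34.5 to 43.3) and the chemokine Cxcl10 at 479 against 333 CPM. Type I interferon members went the other way, with 17 of 20 lower and a median of -0.28 log2 (percentile 0). Some chemokine genes among those named by size were lower, with Ccl2 at 198 against 452 CPM, Ccl7 at 121 against 324 CPM, Cxcl3 at 11.7 against 88.1 CPM and Ccl4 at 56.5 against 133 CPM. The alternative activation list had members that went both ways (median -0.01 log2, percentile 54.4, and -0.26 with each library clustered alone), with the arginase Arg1 at 2754 and 2689 CPM, the folate receptor Folr2 at 176 and 62.1 CPM and the secreted Spp1 at 460 and 895 CPM. Of genes named by size, 50 were higher and 8 lower.

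Cluster 20 supplied 265 of the 911 macrophage-like cells of flfl_CD4Cre and 18 of the 518 of CD4Cre, so among named cells it cannot be told apart from that library. Its top genes were not confined to flfl_CD4Cre, as cluster 12, left unnamed as shallow, had the same 10. Cluster 12 held 28 cells of flfl_CD4Cre, 109 of CD4Cre and 268 of flWT_CD4Cre. Its median was 702 UMIs against 24893 in cluster 20. Without cluster 20, a choice made after seeing the data, 6 genes were higher and 5 lower. The inflammatory list then had 12 of 13 members higher (0.38 log2) and the interferon gamma list 20 of 20 (0.37 log2), while the type I interferon median was -0.04 log2 (percentile 43.75). Dendritic genes were also higher (4 of 4 members, 0.30 log2). B cell (7 of 7 members, -3.67 log2) and neutrophil genes (4 of 5 members, -0.75 log2) were lower. Nos2 stood at 108 against 34.9 CPM, the itaconate enzyme Acod1 at 135 against 50.3 CPM, and Ccl2 at 196 against 458 CPM. Against flWT_CD4Cre, by its label a second Cre library, the interferon gamma list was again higher (0.31 log2, 16 of 20, percentile 99.93). All 20 type I interferon members were lower (-0.85 log2, percentile 0). The inflammatory list was not higher (-0.02 log2, percentile 59.69), and the cell cycle list was lower (-0.34 log2, 25 of 26 members).

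Libraries that both lack Cre by their labels also differed in these lists, though the file name of WT disagrees with its label. In macrophage-like cells of flfl against WT the inflammatory list had 12 of 14 members higher (0.52 log2), the interferon gamma list 18 of 20 (0.34 log2) and the NF-kB list 14 of 15 (0.65 log2), each at percentile 100. Effector genes (8 of 8 higher, 1.13 log2), natural killer genes (1.03 log2) and CD8 lineage genes (3 of 3 higher, 0.59 log2) moved with them, and macrophage markers were lower (-0.16 log2, percentile 0.39). The medians of 0.35 and 0.24 log2 between flfl_CD4Cre and CD4Cre lie below the inflammatory and interferon gamma values of this pair, while the interferon gamma median of 0.37 without cluster 20 and the inflammatory median of 0.89 with each library clustered alone lie above.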

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

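Among the 3 patterns weighed, the tests of macrophage RNA, of read quality by T cluster genes, of T cluster genes with at least 5 CPM and of Ddx60 without 2 libraries were chosen after seeing the result. The other tests were written after the patterns were seen but before their values were computed. The counts and marker levels given below for a response to an Fc protein are part of the pattern itself and had no prediction.

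The first pattern is the pair of library sets, with 80.1921% (Ctrl_Fc) and 80.1201% (PD1_Fc) of reads not aligned. Names of gene models and pseudogenes took 10.2% of gene counts in Ctrl_Fc and 10.3% in PD1_Fc. In Control and PDL1_Fc they took 0.658% and 0.695%, which no test below used. Reads of another organism in Ctrl_Fc and PD1_Fc could leave mouse genes out, and 34.0836% of genes abundant in every single-cell class lay under 10% of that level there against 11.5756% in Control and PDL1_Fc, short of the 3-fold margin set, so that explanation stays open. The first test of poor read quality alone used the same 2 shares and fell between its bounds, and in the later test 26.5385% of 260 genes, abundant in every class and in T clusters and counted in Control and PDL1_Fc, lay under 10% of their T cluster level in Ctrl_Fc and PD1_Fc, against 3.05% of 197 genes the other way, which argues against quality alone. Macrophage RNA in place of T cells in Control and PDL1_Fc is consistent with a macrophage to T marker ratio of at least 525 in each of the 6 libraries. A response to any Fc protein was not tested apart from the set. Between PDL1_Fc, also titled for an Fc, and Control 0 genes passed, with 13452 between Ctrl_Fc and Control. These counts cannot decide it, as the labels give no Fc dose for PDL1_Fc and the protocol names no PD-L1 Fc. Marker levels of Control, whose title names no Fc, argue against it as the source of the macrophage and T marker difference. In each Control library the median of 9 macrophage markers was 94.7 to 120.2 CPM. That of 7 T markers was 0 to 0.0540 CPM, with 1 of the 7 at 10 CPM or more. For other genes it stays open.

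The second pattern is the excess of Lyz2 and mitochondrial reads in Ctrl_Fc_3 and PD1_Fc_1. Carry-over from Control or PDL1_Fc libraries could explain it, and the excess followed the level there with a rho of 0.787946, just short of the 0.8 set before, so it stays open. More mouse T cell RNA in these 2 libraries was first tested by a median log2 ratio of 0 over 52 T cluster genes, which decides nothing as 15 of them had no counts. Over the 25 genes with at least 5 CPM the median was 0.00679 (quartiles -0.13 and 0.06), which argues against the 1 log2 that it needs. No other biological explanation was tested.

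The third pattern is the lower level of the interferon-linked genes Ddx60 and Mx2 in PD1_Fc, while the type I interferon list did not pass, with Ddx60 also apart by -1.24276 log2 from the change in PDL1_Fc against Control. Carry-over of macrophage reads was weighed as a source. It was at a median of 0.472% (Ctrl_Fc_3) and 0.442% (PD1_Fc_1) of the level in Control and PDL1_Fc. With Ddx60 at 50.8 CPM in Control, this is too little for the change, so omission of these 2 libraries could hardly show otherwise. Without Ctrl_Fc_3 and PD1_Fc_1 Ddx60 stayed at -0.88481 log2 (SE 0.24, edgeR adjusted p = 0.288) and Mx2 at -0.88 log2 (SE 0.17, adjusted p = 0.0220). A weaker interferon signal under PD-1 Fc stays open, since the interferon gamma list fell (camera adjusted p = 0.0361) but neither it nor the type I list (0.0819) passed with an estimated correlation (0.884 each). With 4 of 10 splits as large as the real one, the grouping itself is not excluded as the source of these calls.

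Splits of the same 6 libraries into 3 and 3 are 10, too few for a share under 0.05. For PD1_Fc against Ctrl_Fc 4 of 10 splits called at least as many genes as the real 7, and the highest other called 35. The splits with 35, 34 and 33 genes all put Ctrl_Fc_3 and PD1_Fc_1 on the same side, which points to a structure of the samples, although the remaining split of that kind called 3. For lists it was 5 of 10, with 4 real and 7 in the highest other. For PDL1_Fc against Control 10 of 10 splits reached the real 0, with 3 genes in the highest other, and lists gave 10 of 10 with 1 in the highest other. For each comparison across the sets 1 of 10 did, with 0 in the highest other, for 13443 genes (PDL1_Fc against Ctrl_Fc), 13452 (Ctrl_Fc against Control) and 13455 (PD1_Fc against PDL1_Fc). For the difference of differences 44 of 100 splits called at least the real 1 gene, and the highest called 163.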

How the results depend on the processing

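For PD1_Fc against Ctrl_Fc 5 of 14 settings kept the count of 7 within 1.5-fold. Others gave 21 (DESeq2), 27 (only the 6 libraries), 0 by the treatment field, 2 without the 4 conflicting libraries, and 0 to 8 when 1 library was left out. The added omission of Ctrl_Fc_3 and PD1_Fc_1, chosen after seeing the data, gave 5. For PDL1_Fc against Control the count was 0 in 8 of 11 settings, 1 without the gene filter and 0 to 1 with 1 library left out. For the difference of differences DESeq2 gave 10, and 0 to 3 genes were called with 1 library left out. Counts across the sets stayed between 12406 and 15600 in all settings. The replicate block gave 7 genes for PD1_Fc against Ctrl_Fc, and correlations of same-number libraries ran from -0.237 to 0.166 (median -0.0108), so the numbers do not pair the samples.

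The estimated correlation gave 0 lists in every comparison, from 4 for PD1_Fc against Ctrl_Fc, 12 for each comparison across the sets and 2 for the difference of differences. In settings chosen after seeing the data, 6 lists passed with only the 6 libraries and 5 without the 2 libraries, 3 shared each time. The B cell list was lost in both (adjusted p = 0.108 and 0.164).

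Of 687 values of named genes over the alternatives, 623 kept their class, 54 were weaker, 2 stronger and 8 reversed. Reversed were Ddx60 (2.02 log2) and Mx2 (2.72 log2) under the treatment field, which mixes the 2 sets by construction. With 1 library left out Cd80 ran from -3.43 (without PD1_Fc_1) to 0.97 log2, and was -0.10 without Ctrl_Fc_1, while Cd274 ran from -0.31 (without PD1_Fc_1) to 1.35 log2. Without the 2 libraries Cd80 was -3.17. In the difference of differences, Cd274 ran from -0.25 to 1.41 and Cd80 from -3.23 to 1.17 log2, both lowest without PD1_Fc_1. These rest on 2 to 23 counts.

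The B-like share difference of -36.6 points went to -34.6 under the strict filter and to -34.6 with each library clustered alone. The macrophage-like difference of 11.9 points went to 21.9 with each library clustered alone and 9.45 at resolution 2.0. The T lineage difference stayed between -0.904 and -0.751 points. The Cd274 ratio in macrophage-like cells, -0.18 log2, went to -0.32 with each library clustered alone and -0.54 with monocytes, and reversed to 0.0757 without cluster 20, an alternative added after seeing the data like that with monocytes. The inflammatory list went from 0.35 to 0.28 (strict), 0.89 (each alone) and 0.24 log2 (mean over cells), and the alternative list from -0.01 to -0.26 (each alone) and -0.14 log2 (with monocytes). The cause was not tested.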

Other observations

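Control and PDL1_Fc libraries had high levels of genes that activated macrophages express, chosen after their values were seen. The acute-phase gene Saa3 stood at 25668.2 CPM in Control (SD 3981, n = 3) and 24889.8 CPM in PDL1_Fc (SD 577, n = 3), the nitric oxide synthase Nos2 at 3029 and 3134 CPM, and the secreted matrix protein Spp1 at 5822 and 5609 CPM. The antiviral GTPase Mx1 was at 228 and 231 CPM, against 17.5 CPM in Ctrl_Fc and 10.6 CPM in PD1_Fc. Lat, the adaptor of the T cell receptor, was at 21.5 CPM in Control and 17.3 CPM in PDL1_Fc, while Trac had 0 and 3 counts there.

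Cells of cluster 27, the T and natural killer group of the Cre libraries, had less RNA of inhibitory receptors in flfl_CD4Cre than in CD4Cre, with 15 of 17 list members lower and a median of -0.59 log2 (percentile 0.01). The checkpoint receptor Lag3 was at 178 CPM (139 to 225) against 314 CPM (275 to 357), and the exhaustion factor Tox at 146 CPM (110.5 to 188) against 254 CPM (219 to 293). Interferon gamma targets had 18 of 20 members higher (0.57 log2) and receptor activation genes 12 of 18 lower (-0.50 log2). The chemokine Xcl1 was at 128 CPM in flfl_CD4Cre, 549 CPM in CD4Cre and 298 CPM in flWT_CD4Cre, and the granzyme Gzmc had 1, 71 and 3 UMIs. The regulatory factor Foxp3 was at 72.8 CPM (48.7 to 104), 115 CPM (91.6 to 142) and 116 CPM. H2-Aa, an MHC class II gene that T cells lack, was at 40.1 CPM in flfl_CD4Cre and 407 CPM in CD4Cre, and the B cell list was lower by a median of -2.16 log2, so RNA of B cells differs between the libraries in this group too. Natural killer genes were higher (6 of 8 members, 0.66 log2), and dendritic (4 of 4, -2.89 log2) and macrophage genes lower (median -0.73 log2), so the mix of cells in the cluster differs as well and these gene changes are not tied to T cells.

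In the Cre libraries neutrophil-like cells had the most Cd274, at 783 CPM in flfl_CD4Cre, 578 CPM in CD4Cre and 2033 CPM in flWT_CD4Cre against 123 CPM in flfl and 37.3 CPM in WT. Migratory dendritic cells had the most Cd80, at 155, 156 and 184 CPM in the 3 Cre libraries. T-like cells of flfl had more Gzmc than those of WT, at 162 against 7.35 CPM, and more Gzmb, at 186 against 66.7 CPM. The effector list went both ways (9 of 17 members higher, 0.06 log2). Naive and memory genes were lower (14 of 15 members, -0.51 log2), with no Cre in either library by the labels. Macrophage (13 of 13 members lower, -0.73 log2), B cell (9 of 9 lower, -1.44 log2) and neutrophil genes (6 of 7 lower, -0.51 log2) moved with them.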
